A study of Mus musculus with 96 samples.

How the data were processed

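Total RNA from gonadal fat and liver of 48 F2 mice of an M16i x MB2 intercross, all 15 weeks old, had been hybridised as biotin-labelled cRNA to Illumina bead arrays. Each mouse gave 1 fat and 1 liver array, 96 arrays in all. The labels give the tissue, sex, haplotype class (1 to 4), scanning day and mouse number of every array, and groups were taken from them. They do not say which parental segments each haplotype class carries, so the classes are named by number throughout. Each tissue had 12 arrays per class, 6 of each sex, and 4 scanning days with 12 arrays each, 3 per class. Within a scanning day, the 3 arrays of a class came from mice of 1 sex. The mouse numbers of the labels pair the fat and liver arrays of the same animal. That pairing entered as a random block in alternatives only, with limma's duplicateCorrelation.

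The deposited signal table holds bead-summarised probe intensity values that the authors had neither background-corrected nor normalized. A second deposited column per array, headed as a detection p-value in the file, holds 1 minus the p-value, since it rises with the signal. It was turned back before use. The deposited matrix holds values on a log2-like scale that the authors had transformed and normalized, apparently within each tissue. The submitters' processing notes name lumi for it, and its version, transformation and normalization method are not given in the sources used here. Array medians of the deposited log2 values were 7.21 to 7.24 in fat and 7.55 in liver. The matrix served as an alternative only.

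Signals were processed in R 4.3.3 with limma 3.58.1. The neqc function subtracted background with the normexp model fitted from the detection p-values, added an offset of 16, quantile-normalized the arrays and took log2. It was run within each tissue for the tests by class and sex, and over all 96 arrays together for the tests that compare the tissues, so that fat or liver levels differ slightly between the 2 settings. A probe was tested in a tissue if its detection p was under 0.01 on at least 12 arrays, which kept 10217 probes in fat and 8504 in liver. Over both tissues together, the same minimum kept 11718 probes. Signals near background are compressed by the offset, so that a difference between a detected and an undetected group understates the change.

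Linear models were fitted with lmFit and eBayes with a mean-variance trend. Haplotype class was tested with a moderated F-test over the 4 classes, and sex as female minus male, in a model with class, sex and scanning day. The pairwise class differences came from the same model, and the interaction of sex and class was a moderated F-test on 3 terms. Fat minus liver was tested with sex and class as terms, because scanning day is nested in tissue. The interactions of tissue with class and with sex had scanning day as a further term. Benjamini-Hochberg adjusted p-values under 0.05 were called. Levels are given as log2 means adjusted for the other terms, and SDs are those of values from which sex and scanning day (for sex, class and scanning day) had been removed. In the comparison of the tissues, the SDs are those of all 48 arrays of a tissue. As a check within batches, the direction of each named gene was counted over the 4 scanning days of its tissue. For class, this is the number of days on which the class with the highest mean exceeded the class with the lowest, and each such cell of 3 arrays holds 1 sex. All tests of sex and class were two-sided.

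The array has 46116 probes, of which 29534 had 1 gene symbol in the deposited platform table, 11 had several and 16571 had none. Of the named probes, 29476 matched a gene of the reference table of the GRCm38.p6 assembly. That table was used for the names, chromosome and order of genes only, and no coordinates are given, since no build is named in the files. Where several probes of a gene were tested, the probe with the highest mean over the tissue's arrays stood for the gene, and other probes were compared in direction. Probes for members of the Cyp2a, Cyp2b, Cyp3a, Cyp4a, Cyp2d, Mup, Sult2a and Gstp families can bind transcripts of close paralogs, so that the member named is uncertain.

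Genes were named by a rule set before the data were examined. For class, these were the 14 genes on chromosome 2 and the 8 elsewhere with the largest difference between the highest and the lowest class among those past the threshold. For sex, they were the 12 genes with the largest difference in each direction, and for tissue the 10 largest in each direction. For interactions, the 5 smallest p-values past the threshold were named, or the smallest if none passed. For each list, up to 4 members with the largest moderated statistic were named, and for the list of chromosome 2 candidates every member past the threshold. Xist and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were always examined to check the sex labels. Where a probe had no signal above background on any array of a group, the fold is given as a lower bound. It sets the bright group's mean over all its arrays against the dim group's mean of, per array, the higher of the lowest signal among detected probes and the probe's own.

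The share of class genes on chromosome 2 and the overlap of the tissues were tested with Fisher's exact test, two-sided, on 1 probe per gene. For each class gene on chromosome 2, the way of parting the 4 classes into 2 sets that held the largest share of the variation between classes was recorded. Lists of genes, also fixed before the data were examined, cover adipocyte and adipokine genes, adipose expansion markers, lipogenesis, cholesterol synthesis, fatty acid oxidation, oxidative phosphorylation, gluconeogenesis and insulin response, bile acid and sterol transport, thermogenic fat genes, macrophages, lymphocytes, interferon response, extracellular matrix, acute phase, unfolded protein response, liver genes known as female-biased or male-biased, X inactivation and escape, Y chromosome, ovary, testis and epididymis, mesothelium, pancreas, red blood cells, hepatocytes, skeletal muscle, immediate early genes, circadian clock, growth hormone and IGF axis, preadipocytes and stroma, endothelium, proliferation, and metabolic candidates on chromosome 2. Lists with at least 3 tested members were tested by sex with limma's camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives. They were tested by class with 1e+05 permutations of the class labels within sex on the mean of standardised values from which sex and scanning day had been removed. Exchanging them within sex and scanning day was an alternative chosen after seeing the data. Adjustment was over the lists of a tissue.

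Alternatives, whose effects are in the closing section, were the deposited matrix, no background correction, normalization over all arrays, no detection filter and a stricter one, other terms for scanning day, the first digit of the mouse number as a term, array weights, leaving out each scanning day, each sex alone, the mouse or the scanning day as a random block, median centring, a threshold of 0.01 and all probes counted singly. The least correlated arrays, the share of detected probes and male fat arrays with testis and epididymis genes gave alternatives chosen after seeing the data. The steps were tested on simulated data with the residual spread of these arrays. A log2 difference of 0.25 was recovered for 61.2% of changed probes for class in fat and 71.6% for class in liver, and a difference of 0.5 for 95.5% and 94.0%. For class, the simulated difference set classes 1 and 2 against classes 3 and 4. A difference that sets 1 class apart was not simulated and would be recovered less often. More probes were changed than were called by class in the real data, which also eases the adjusted threshold. For sex, a difference of 0.25 was recovered for 79.1% in fat and 80.6% in liver. Of the calls in simulated data, 14 of 185 were false for class in fat, 2 of 179 for class in liver, 7 of 186 for sex in fat, 10 of 194 for sex in liver and 13 of 204 for tissue. In the simulated list tests in liver, 3 of 4 calls by class and 1 of 2 by sex were lists other than the shifted one. In fat 0 of 1 were in either test. Probes shifted singly in the same data had been left among their members. The number of arrays limits the precision of every value. No per-sample column was left unused, and genotypes and body measurements were not analysed here.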

Results

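Gonadal fat and liver were profiled in 48 mice of an F2 intercross between M16i, an inbred line derived from the M16 line that was selected for growth, and MB2. The stated purpose was to find expression QTLs in an obesity study of mouse chromosome 2. Each tissue had 48 arrays, 12 for each of 4 haplotype classes and 24 for each sex. The number of probes detected above background ranged from 6582 to 10002 per fat array (median 9226) and from 5519 to 9060 per liver array (median 7456.5). Mean numbers of detected probes were alike in the 4 classes, between 8720.25 and 9129 in fat and between 7370 and 7620.5 in liver. Median raw signals were 85.9 to 212.8 in fat and 108.2 to 196.9 in liver. Scanning day had a strong effect, with 5644 of the 10217 fat probes (55.2%) and 4872 of the 8504 liver probes (57.3%) differing between days, and was a term in every test within a tissue. The sex labels fitted Xist, the RNA that silences an X chromosome in females. Its log2 signal lay between 8.18 and 10.35 in female fat and between 5.78 and 6.05 in male fat, and in liver between 6.83 and 9.17 in females and between 6.04 and 6.18 in males. Probes for the Y-linked genes Eif2s3y, Kdm5d and Uty stayed near background in both sexes, and Ddx3y had no probe.

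One question was which transcripts differed between the haplotype classes in fat. Slpi, which encodes a secreted protease inhibitor that restrains inflammation, had the widest range. Its level was 9.31 (SD 0.99, n = 12) in class 1, 10.07 (SD 0.73, n = 12) in class 2, 6.94 (SD 0.59, n = 12) in class 3 and 9.35 (SD 0.77, n = 12) in class 4, an 8.75-fold difference between classes 2 and 3 (adjusted p = 1.11e-08). Pdrg1, linked to the response to DNA damage, was near 7.3 in classes 1 and 2 (7.25, SD 0.61, and 7.32, SD 0.47) and lower in class 3 (6.35, SD 0.56) and class 4 (6.01, SD 0.43), where 6 and 2 of the 12 arrays detected it (adjusted p = 4.9e-05). Gchfr, the feedback regulator of the enzyme that starts tetrahydrobiopterin synthesis, ran the other way, from 6.14 in class 1, with 3 arrays above background, to 7.11 in class 4 (adjusted p = 1.4e-05). Stard7, a carrier of phosphatidylcholine to mitochondria, fell from 7.18 (SD 0.16) in class 1 to 6.35 (SD 0.07) in class 4, with classes 2 and 3 between them at 6.69 and 6.73 (adjusted p = 1.97e-11). Tmem87a, a Golgi membrane protein gene, was 9.33 (SD 0.18) in class 1 and 8.51 (SD 0.13) in class 4 (adjusted p = 1.98e-11).

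In limma's F-test 41 fat probes, of 36 named genes and 4 probes without a name, differed between the classes, against 1323 at an unadjusted p under 0.05. The genes on chromosome 2 with the next widest ranges were Rbbp9 (7.80 in class 1 and 6.99 in class 4), Ttc17 (7.49 and 6.73), Tmem127 (7.56 and 6.79), the endocytic gene Ehd4 (9.33 and 8.67), Itpripl1 (7.04 and 6.41), the immune signalling gene Traf6 (6.42 and 5.98, detected on 12 and 0 arrays) and Eif3j1 (6.41 and 5.97), all highest in class 1 and lowest in class 4. Ywhab, a 14-3-3 protein gene, was lowest in class 2 at 10.91 (SD 0.17), against 11.37 to 11.51 in the others (adjusted p = 0.000423). Manbal was lower in classes 1 and 2 (9.04 and 8.99) than in classes 3 and 4 (both 9.34, adjusted p = 0.0185). For each of these 14 genes, the highest class exceeded the lowest on 4 of 4 scanning days. Second probes of Tmem87a, Tmem127 and Ehd4 lay near background in fat and did not differ (adjusted p of 0.815, 0.576 and 0.426). Manbal did not pass without any 1 of the 4 days, Eif3j1 without day 3, 7 or 8, and Itpripl1 without day 8, each of which left 9 arrays per class.

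Fat also had 15 class genes on other chromosomes, and all 15 were lowest in class 2. Lgals1, the gene of the lectin galectin-1, was 12.79 (SD 0.29) in class 2 against 13.21 to 13.35 in the other classes (adjusted p = 0.00253). Sncg, which encodes gamma-synuclein, was 11.22 (SD 0.46) in class 2 and 12.01 (SD 0.27) in class 4 (adjusted p = 0.0218). Timp4, a metalloprotease inhibitor gene, was 8.43 (SD 0.54) in class 2 and 9.37 (SD 0.37) in class 3 (adjusted p = 0.0412), and Tmem45b was 11.46 (SD 0.63) and 12.40 (SD 0.43) in the same classes (adjusted p = 0.0442). These last genes kept the order on 3 of 4 scanning days. Fez2 (7.30 in class 2 and 7.85 in class 4), Cela1 (6.55 and 7.15 in class 3), Anxa6 (10.54 and 11.04 in class 3) and the extracellular superoxide dismutase gene Sod3 (6.67 and 7.26 in class 3) kept it on 4 of 4. The other members were Rab7, Rtn4, Map7d1, Parp3, Meox1, Rtn4rl1 and Rps6ka3, of which further Rab7 probes did not pass (adjusted p of 0.527 and 0.334). Of the 8 genes with the widest ranges, 3 did not pass in limma without day 3, 6 without day 4, 7 without day 7 and all 8 without day 8. Without the 3 fat arrays least correlated with the rest, an alternative chosen after seeing the data, 4 of the 15 passed. All 15 had an unadjusted p of 0.00192 or less in that F-test. They had been chosen by the same test on arrays that include these, so the small p-values are not separate support. Between pairs of classes, limma called 142 probes for classes 2 and 4, 18 of them on chromosome 2, and 43 for classes 2 and 3. Classes 1 and 4 differed at 18 probes, all on chromosome 2. The remaining pairs gave 7 (classes 1 and 2), 3 (1 and 3) and 7 (3 and 4).

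**Figure D1:**
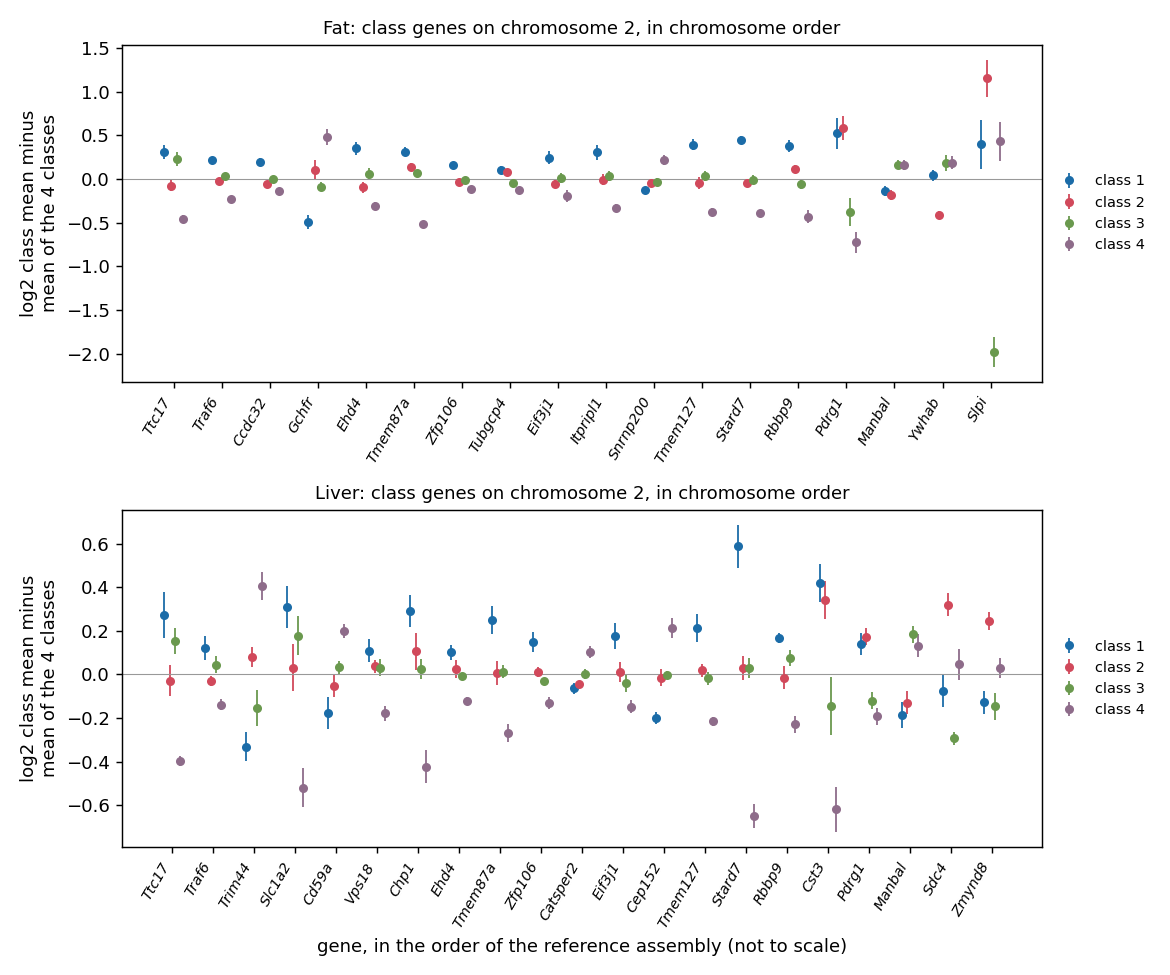
Log2 mean of each haplotype class minus the mean of the 4 classes, for the chromosome 2 genes that differed between classes in fat (top, 18 genes) and liver (bottom, 21 genes), in the order of the reference assembly; points are means of 12 arrays and bars are standard errors. Class 1 and class 4 lie at opposite ends for most genes, while Slpi in fat is set apart by class 3 (6.94, against 9.31 to 10.07 in the others).

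In liver the same question was asked of 8504 probes. Stard7 had the widest range and again fell from class 1 to class 4, from 7.97 (SD 0.34, n = 12) through 7.41 in classes 2 and 3 to 6.73 (SD 0.19, n = 12; adjusted p = 5.82e-11). Cst3, the gene of the secreted protease inhibitor cystatin C, was 10.73 (SD 0.30) and 10.65 (SD 0.30) in classes 1 and 2, 10.16 (SD 0.47) in class 3 and 9.69 (SD 0.36) in class 4 (adjusted p = 1.63e-05). Slc1a2, a glutamate transporter gene, was 8.05 (SD 0.30) in class 4 and 8.60 to 8.88 in the others (adjusted p = 0.000735), and the call was lost when day 2 was left out. Trim44 went the opposite way, from 8.33 (SD 0.23) in class 1 to 9.07 (SD 0.22) in class 4 (adjusted p = 1.63e-05), as did the centrosome gene Cep152, from 6.23, with 4 arrays above background, to 6.64 with 11 (adjusted p = 1.04e-05), and Cd59a, which protects cells from complement, from 9.75 to 10.12 (adjusted p = 0.0408). Sdc4, a heparan sulfate proteoglycan gene, was highest in class 2 (9.85, SD 0.19) and lowest in class 3 (9.23, SD 0.10; adjusted p = 0.000175).

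The liver F-test called 27 probes, of 23 named genes and 3 probes without a name, against 455 at an unadjusted p under 0.05. Further genes with wide ranges were Chp1 (10.94 in class 1 and 10.22 in class 4), Ttc17 (7.35 and 6.68), Tmem87a (7.45 and 6.93), Tmem127 (6.89 and 6.46) and Rbbp9 (6.96 and 6.56), each lowest in class 4. Zmynd8 was highest in class 2 (7.98, SD 0.15), and Manbal was lower in classes 1 and 2 (7.35 and 7.41) than in classes 3 and 4 (7.72 and 7.67). All 14 of these liver genes kept the order of the extreme classes on 4 of 4 scanning days. Zmynd8 and Cd59a did not pass without day 2, 5 or 6, and Manbal did not pass without day 1 or 2. Second probes of Tmem127 and Chp1, near background, did not pass in liver (adjusted p of 0.999 each). Classes 1 and 4 differed at 27 probes, 23 of them on chromosome 2, and the other pairs at 1 to 9 probes.

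Class genes were concentrated on chromosome 2 in both tissues. In fat, 18 of the 33 class genes with a known chromosome lay on it, which is 54.5% against 7.72% of the tested genes (odds ratio 14.8, 95% interval 7.00 to 31.7; Fisher's exact p = 2.5e-12). In liver all 21 did, against 7.59% of the tested genes (lower limit of the odds ratio 66.1; Fisher's exact p = 1.96e-24). Neighbouring genes tend to be inherited and expressed together, so these genes are not independent. The fat genes spanned positions 243 (Ttc17) to 457 (Slpi) among the 530 tested genes of the chromosome, and the liver genes positions 209 (Ttc17) to 391 (Zmynd8) of 442. Among the fat genes, class 1 stood apart from the other classes for 6, class 4 for 5, class 2 for Ywhab and class 3 for Slpi. Classes 1 and 2 stood against 3 and 4 for 3 genes (Tubgcp4, Pdrg1 and Manbal), and classes 1 and 3 against 2 and 4 for Ttc17 and Gchfr. Among the liver genes class 4 stood apart for 11, and no gene in either tissue set classes 1 and 4 against 2 and 3.

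**Figure D2:**
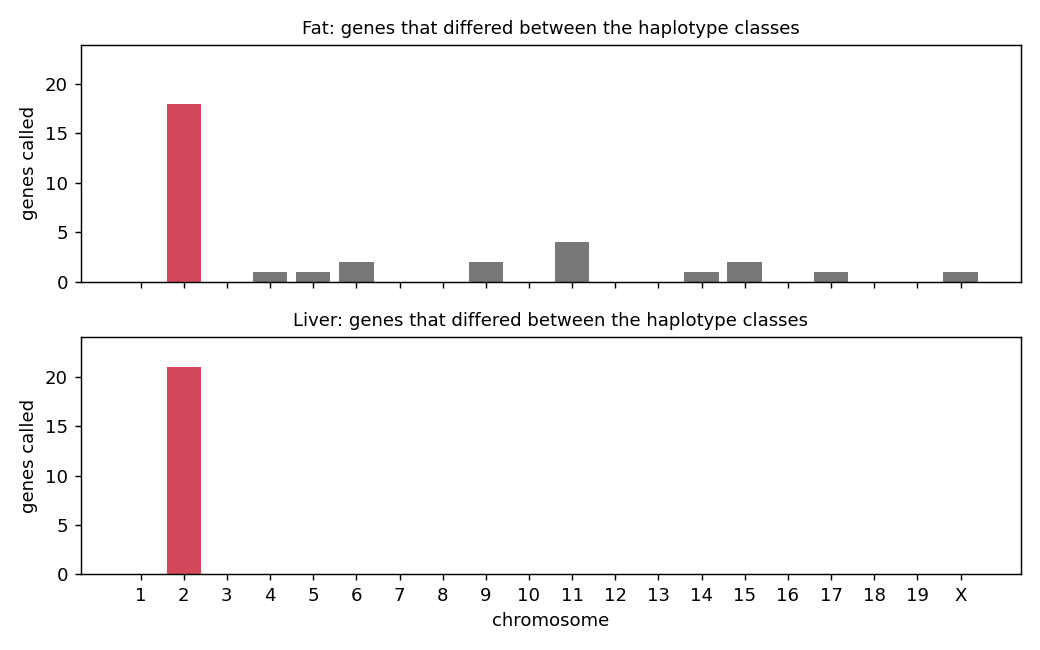
Number of genes that differed between the 4 haplotype classes (limma F-test) by chromosome, in fat (top) and liver (bottom). Chromosome 2, drawn in red, holds 18 of 33 genes in fat and 21 of 21 in liver.

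The tissues shared 11 class genes, all on chromosome 2: Pdrg1, Stard7, Tmem87a, Rbbp9, Ttc17, Tmem127, Ehd4, Traf6, Eif3j1, Manbal and Zfp106. Among 5151 genes tested in both, 25 had been called in fat and 20 in liver, so that 0.0971 shared genes were expected of independent lists (Fisher's exact p = 4.36e-22). The same mice gave both tissues, so the lists do not come from independent animals. Class genes of both tissues were concentrated on chromosome 2, so the number expected over all genes is lower than it would be within that chromosome. Class 1 had the highest level in both tissues for 9 of the 11, class 2 for Pdrg1 and class 3 for Manbal. Across the 24 chromosome 2 genes tested in both tissues and called in either, the class means of fat and liver, centred per gene, had a Pearson correlation of 0.553. Genes tested in 1 tissue only, such as Slpi and Slc1a2, are not among them. It was 0.0798 across the other chromosome 2 genes, 0.0954 across the 10 class genes of other chromosomes that were tested in both tissues, and 0.0872 across all genes of other chromosomes. These correlations are across genes, which are not independent replicates.

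Whether a class effect differed between the tissues was tested directly. The interaction passed for 21 probes, 10 of them on chromosome 2, against 939 at an unadjusted p under 0.05. For Slpi the class means spanned 6.85 to 10.12 in fat and 5.99 to 6.49 in liver, where 11 of 48 arrays detected it (adjusted p = 2.14e-07). Cep152 varied in liver only, from 6.21 to 6.80, and stayed close to the mean of 6.18 in fat (adjusted p = 2.94e-07). Gchfr rose from 6.17 in class 1 to 6.96 in class 4 in fat while its class means lay between 9.79 and 9.90 in liver (adjusted p = 1.61e-05). A second Gchfr probe, chosen after its values were seen, had a smaller p (3.14e-13 adjusted), with 5.97 in class 1 and 6.46 in class 4 in fat and 9.61 and 9.08 in liver. Cst3 fell from 10.62 to 9.68 in liver and lay between 12.80 and 12.92 in fat (adjusted p = 3.53e-05). Slc1a2 was not detected on any fat array and ranged from 8.27 to 8.98 in liver (adjusted p = 0.000315).

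A further question was whether class effects differed between the sexes. No probe passed the interaction of sex and class in limma in either tissue, against 685 probes in fat and 573 in liver at an unadjusted p under 0.05. The smallest p was that of Tmem63b in fat (adjusted p = 0.627) and of the UFM1 ligase gene Ufl1 in liver (adjusted p = 0.192). Without scanning day in the model, limma called 3 probes in fat and 316 in liver. Each class and day held mice of 1 sex, so that day and this interaction are partly tied.

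None of the 27 gene lists tested by class in fat, and none of the 24 in liver, passed in the permutation test, and the deposited values also gave 0 and 0. In fat 3 lists had an unadjusted permutation p under 0.05. They were extracellular matrix (p = 0.0149, adjusted p = 0.351), macrophage and inflammation (p = 0.026, adjusted p = 0.351) and adipose expansion markers (p = 0.0418, adjusted p = 0.368), each lowest in class 2. Exchanging class labels within scanning day as well, an alternative chosen after seeing the data, gave the macrophage list an unadjusted p of 0.0642. Leptin (Lep), a marker of fat mass, was 10.90 in class 2 and 12.12 in class 3, without passing (adjusted p = 0.148). In liver only the list of genes known as male-biased had an unadjusted p under 0.05 (permutation p = 0.00848, adjusted p = 0.203), and it was lowest in class 4. Of the metabolic candidates on chromosome 2, 34 were tested in fat and 27 in liver. The count that differed by class was 0 in both tissues, and 0 when adjusted over the list alone.

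Sex differences in liver were large. A1bg, the gene of a plasma glycoprotein, averaged 13.64 (SD 0.64, n = 24) in females and 6.25 (SD 0.17, n = 24) in males, of which 3 detected it (difference 7.39, SE 0.15, adjusted p = 1.55e-37). The sulfotransferase gene Sult2a2 was detected in 24 females and 0 males and was at least 83.6-fold higher in females (adjusted p = 1.02e-53). Hamp2, related to the iron hormone hepcidin, was 13.84 (SD 0.66) in females and 8.97 (SD 1.39) in males (adjusted p = 4.05e-16). Males had more Cyp4a12a, a fatty acid hydroxylase gene, at 12.15 (SD 0.18) against 6.16 (SD 0.09) in females (difference -5.99, SE 0.05, adjusted p = 1.02e-53). Hsd3b5, which acts on steroid hormones, was at least 47.6-fold higher in males and was detected in 0 of 24 females (adjusted p = 4.34e-42). Cyp7b1, an oxysterol hydroxylase gene, was 11.78 (SD 0.43) in males and 7.45 (SD 0.47) in females (adjusted p = 1.04e-28).

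The liver test called 2893 probes (34.0% of those tested), 1417 higher in females and 1476 higher in males. More than 2-fold differences were found for 69 probes higher in females and 66 higher in males. Other genes high in females were the cytochrome P450 genes Cyp2b9 (difference 4.79), Cyp2a5 (4.50), Cyp2a4 (3.70), Cyp2c39 (3.42), Cyp3a41a (2.59) and Cyp4a10 (2.54), the metallothionein gene Mt1 (2.51), and Cyp2b13 and Hao2, which were at least 17.9-fold and 4.79-fold higher with 0 of 24 males above background. Genes high in males included Cyp2d9 (-3.89), Tff3 (-3.49), Nat8 (-2.97), the urinary protein gene Mup2 (-2.85), the complement gene C6 (-2.74), Ttc39c (-2.59), Gstp1 (-2.58), the heme synthesis gene Alas2 (-2.45) and Susd4 (-2.40). All 24 named genes kept their direction on 4 of 4 scanning days.

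Among the lists, all 18 tested liver genes known as female-biased were higher in females and 20 of the 21 known as male-biased were higher in males (camera adjusted p = 2.6e-36 and 4.87e-36), with the same counts adjusted over the list alone. The 3 tested X inactivation and escape genes, Xist, Eif2s3x and Kdm6a, were higher in females (adjusted p = 5.68e-05). These 3 lists were the only ones in liver to pass with an estimated correlation as well. Fatty acid oxidation had 9 of 14 genes higher in females, among them Ehhadh (1.23), Cyp4a14 (1.85) and Acadm (0.34), 5 not passing, and 10 adjusted over the list alone (adjusted p = 0.000293, but 0.204 with an estimated correlation). Unfolded protein response had 5 of 10 genes higher in males, Creld2 (-1.77), Pdia4 (-0.51), Hyou1 (-0.49), Xbp1 (-0.42) and Sel1l, and 5 adjusted over the list alone (adjusted p = 0.00508, but 0.236 with an estimated correlation). Of the hepatocyte genes 6 of 14, such as Apoa2 (0.30) and Ahsg (0.44), were higher in females, and 8 adjusted over the list alone (adjusted p = 0.0186, but 0.103 with an estimated correlation). In gluconeogenesis and insulin response 5 of 9 genes were higher in females, with Got1 (0.87), Gpt, Fbp1 and Ppargc1a in front, and 5 adjusted over the list alone (adjusted p = 0.0213, but 0.204 with an estimated correlation). With fry, which asks only whether a list moves one way, 13 liver lists passed.

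The other liver lists did not pass in camera. Bile acid and sterol transport had 6 of 13 genes higher in females, such as Abcg5 (0.62), and 3 higher in males, with Cyp7b1 first (9 adjusted over the list alone), and its median (0.17) and mean (-0.20) differed in sign while the test pointed up. Lipogenesis had 5 of 18 higher in females and 1, Thrsp (-0.88), in males (6 adjusted over the list alone), and cholesterol synthesis 2 of 16 in each direction (4 adjusted over the list alone). Macrophage and inflammation had 3 of 7 higher in females, among them Clec4f (0.63; 4 adjusted over the list alone), and endothelium 3 of 7 (4 adjusted over the list alone). The growth hormone and IGF axis had Socs2 (1.09), Igfals and Igfbp3 higher in females and Ghr in males, 4 of 8 (5 adjusted over the list alone). Acute phase had Apcs (0.78) higher in females and 3 of 13 higher in males (4 adjusted over the list alone), and its median (0.01) and mean (-0.08) differed in sign. Oxidative phosphorylation had 2 of 25 higher in females and 1 in males (3 adjusted over the list alone), with a median of -0.02 and a mean of 0.01. The interferon response had 1 of 7 higher in females, Gbp3 (0.53; 1 adjusted over the list alone), with a median of -0.03 and a mean of 0.04. Adipocyte and adipokine genes had Agt (1.45) and Nampt higher in females and Lpl (-1.06) and Cebpa in males (4 of 6 adjusted over the list alone), and extracellular matrix had 2 of 7 in each direction (4 adjusted over the list alone). Red blood cells had 1 of 4, Alas2, higher in males, circadian clock 2 of 11 higher in males (Clock and Nr1d2), immediate early genes 1 of 4 higher in females (Egr1, 1.35), proliferation 1 of 3 higher in females (Mki67), and preadipocyte and stroma 0 of 4. Adjusted over the list alone these counts were 1, 2, 2, 1 and 0. Of the metabolic candidates on chromosome 2, 8 of 27 were higher in females (Id1, Pltp, Mertk, Pdk1, Lrp4, Foxa2, Idh3b and Acss2) and 3 in males (Prnp, Agpat2 and Rxra), 11 adjusted over the list alone.

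Fat differed between the sexes as well. The labels call the fat gonadal, and the gonads differ by sex, so that sex and the site of the pad cannot be separated here. Xist was at least 8.02-fold higher in females and not detected in males (adjusted p = 3.09e-24). Spon2, a matrix protein gene, was 10.57 (SD 0.73, n = 24) in females and 8.13 (SD 0.60, n = 24) in males (difference 2.43, SE 0.21, adjusted p = 6.36e-12). The matrix genes Thbs2 (1.42) and Lum (1.33) and the leukocyte gene Lsp1 (1.37) were also higher in females, as was the muscle actin gene Acta1, at 9.17 with a wide spread (SD 1.75) against 6.75 (SD 0.72; adjusted p = 2.98e-05). Males had more RNA of the plasma proteins lipocalin-2, haptoglobin and ceruloplasmin. Lcn2 was 8.57 (SD 1.75) in males and 6.28 (SD 0.62) in females (difference -2.29, SE 0.41, adjusted p = 5.55e-05), Hp was 13.01 (SD 0.38) and 11.81 (SD 0.56; adjusted p = 7.01e-08), and Cp was 7.83 (SD 0.52) and 6.54 (SD 0.23; adjusted p = 3.23e-10).

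The fat test called 2314 probes (22.6%), 1241 higher in females and 1073 higher in males, and 61 differed by more than 2-fold (27 and 34). Further genes high in females were Rnase2a (1.49), Kng1 (1.46), Ngfr (at least 2.25-fold, detected in 20 females and 0 males), Fgf13 (1.28), Bmp3 (1.23) and Mrvi1 (1.19). Genes high in males were Ecrg4 (-1.66), the growth factor gene Gdf10 (-1.66), Apod (-1.63), Calml3 (at least 2.33-fold, detected in 13 males and 0 females), Sox9 (-1.54), Gpnmb (-1.54), Cyp1b1 (-1.37), Ltbp2 (-1.32) and Slpi (-1.29). The direction held on 4 of 4 scanning days for all of these except Slpi, for which it held on 3. Apod, Calml3 and Gpnmb did not pass without day 3, and Gpnmb did not pass without day 8 either. No gene of the testis and epididymis list was detected on 12 fat arrays, but 4 male fat arrays detected at least 5 of them, and Calml3 was above background on all 4 of these. The most detected on a female array was 1.

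**Figure D3:**
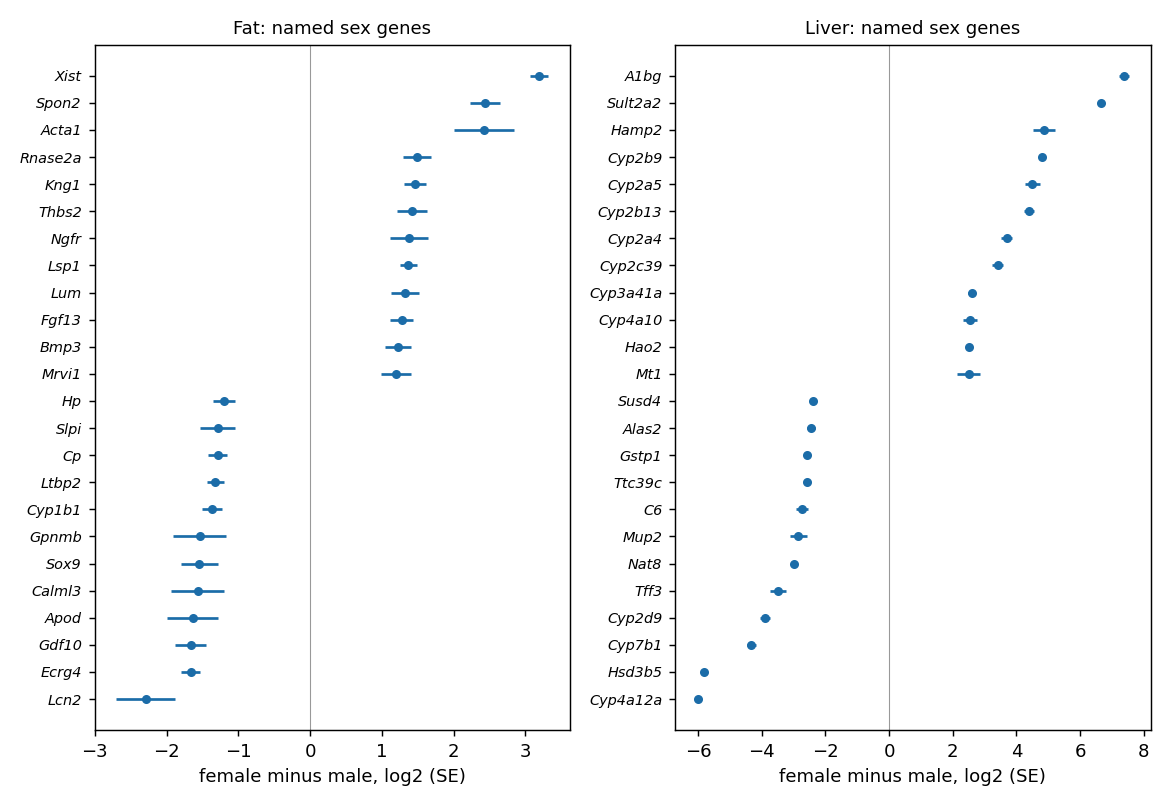
Log2 difference, female minus male, for the 24 named genes of each tissue (points, with standard errors as bars; some bars are smaller than the points), from 24 arrays per sex. Differences reach 7.39 (A1bg) and -5.99 (Cyp4a12a) in liver, against 3.20 (Xist) and -2.29 (Lcn2) in fat, and are fitted values that understate genes not detected in 1 sex.

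In fat 7 of 27 lists passed by sex in camera. X inactivation and escape (3 of 3 genes higher in females, adjusted p = 6.98e-11), preadipocyte and stroma, and hepatocyte genes did so with an estimated correlation as well. Preadipocyte and stroma had 8 of 9 genes higher in females, among them Thy1 (1.15), Cd34 (0.53) and Pdgfrb (0.30), and 9 adjusted over the list alone (adjusted p = 1.6e-07). The hepatocyte list had 4 of 5 genes higher in males, Cyp2e1 (-0.85), Trf (-0.55), Hnf4a (-0.47) and Serpina1a (-0.30), and 4 adjusted over the list alone (adjusted p = 0.00915), and Cyp2e1 and Trf were abundant in fat of both sexes (12.02 and 11.51 in females). Extracellular matrix had 11 of 13 genes higher in females, such as Col1a1 (1.10), Lox (0.78), Col6a1 (0.66) and Mmp2, and 11 adjusted over the list alone (adjusted p = 2.9e-07, but 0.0833 with an estimated correlation). Cholesterol synthesis had 7 of 11 genes higher in males, with Msmo1 (-0.68), Hmgcs1 (-0.41) and Sqle (-0.29), and 7 adjusted over the list alone (adjusted p = 0.00204, but 0.367 with an estimated correlation). Endothelium had 5 of 9 genes higher in females, among them Pecam1 (0.38), Eng and Esam, and 5 adjusted over the list alone (adjusted p = 0.013, but 0.367 with an estimated correlation). In oxidative phosphorylation 3 of 25 genes passed, Ndufb8 (-0.29), Ndufv1 and Atp5b, all higher in males, and 2 adjusted over the list alone (adjusted p = 0.0206, but 0.626 with an estimated correlation). With fry 11 fat lists passed, and oxidative phosphorylation was not among them.

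The remaining fat lists did not pass in camera. Of the adipocyte and adipokine genes 4 of 17 were higher in males (Agt, -0.66, Nampt, Plin1 and Plin4) and Lpl in females (6 adjusted over the list alone). Among adipose expansion markers Bmp3 was higher in females and Nnat (-0.93) and Cav2 in males, of 8 (3 adjusted over the list alone). Lipogenesis had Acss2 (0.96) and Elovl6 higher in females and 3 of 16 in males, with Pnpla3 (-1.03) and Acacb first (9 adjusted over the list alone), and its median of -0.00253 and mean of 0.01 differed in sign. Fatty acid oxidation had 4 of 9 higher in males, such as Acadm (-0.32), and Pdk4 in females (5 adjusted over the list alone). Gluconeogenesis and insulin response had Irs1 (0.62) and Pdk4 higher in females, of 7 (2 adjusted over the list alone), and thermogenic fat genes had Cox8b (0.80) and Cox7a1, of 3 (2 adjusted over the list alone). Macrophage and inflammation had Gpnmb and Cd9 higher in males and Mrc1 in females, of 11 (6 adjusted over the list alone). Acute phase had Orm1 (0.66) and Orm2 higher in females and Lcn2, Hp and Cp in males, of 7 (7 adjusted over the list alone). Mesothelium had Wt1 (0.91) higher in females and Krt8 (-0.97) and Krt18 in males, of 7 (4 adjusted over the list alone). The growth hormone and IGF axis had Socs2 and Igfbp3 (0.80) higher in females and Cish (-0.70) in males, of 8 (3 adjusted over the list alone). Circadian clock had Tef (-0.55) and Bhlhe40 higher in males, of 11 (2 adjusted over the list alone). The unfolded protein response had 1 of 11 higher in females (Chac1), with a median of -0.04 and a mean of 0.02 (1 adjusted over the list alone). Red blood cells had 1 of 4 higher in males, Hba-a1 (2 adjusted over the list alone). Liver genes known as female-biased had 2 of 3 higher in males in fat (Prom1, -1.11, and Abcd2) and Rtn4 in females (3 adjusted over the list alone), and those known as male-biased had Egfr (-0.47) higher in males, of 7 (1 adjusted over the list alone). T and B lymphocytes (5 tested, median 0.09, mean -0.06), interferon response (5), immediate early genes (7) and proliferation (5) had 0 genes past the threshold, and 0 adjusted over the list alone. Of the metabolic candidates on chromosome 2, 6 of 34 were higher in females (Tgm2, Prnp, Acss2, Mapre1, B2m and Mdk) and 8 in males (Lcn2, Nnat, Agpat2, Mertk, Pltp, Pygb, Hnf4a and Lrp2), 14 adjusted over the list alone.

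Lists with fewer than 3 tested genes were not tested as lists. Pancreas had 2 genes in each tissue, Cela1 higher in males and Amy2a5 higher in females in both. Skeletal muscle had Acta1 and Myl1 in fat, of which Acta1 passed, and 0 in liver. Ovary had Hsd3b1 in each tissue, at -0.04 in liver with an adjusted p of 0.0396. Bile acid and sterol transport had 2 genes in fat, and neither passed. In liver, adipose expansion had 2 genes and neither passed, thermogenic genes had Pank1 higher in females and Elovl3 (-1.31) higher in males, and mesothelium had Krt18 higher in males. Testis and epididymis and Y chromosome genes had 0 in both tissues, and T and B lymphocytes had 0 in liver.

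Among genes tested in both tissues, 1116 were called by sex in fat and 1754 in liver. Of these 142 were higher in females in both and 126 higher in males in both, against 85.3 and 105.2 for independent lists. Opposite directions made up 41.1% of the genes called in both, against 49.9% for independent lists (odds ratio of being called in both 1.45, Fisher's exact p = 1.23e-07). The correlation of the differences across genes was 0.0521. The interaction of tissue and sex passed for 3243 probes. Sult2a2 (adjusted p = 3.33e-88), Hsd3b5 (3.35e-69), Cyp2b9 (6.88e-61), A1bg (6.96e-59) and the organic anion transporter gene Slc22a26 (1.69e-56) had the smallest p. Each was near background in fat and strongly sex-biased in liver, where the difference was 6.56 for Sult2a2, -5.73 for Hsd3b5, 4.73 for Cyp2b9, 7.17 for A1bg and 2.70 for Slc22a26.

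Fat and liver were compared as a check of the tissue labels. Adiponectin (Adipoq), a hormone of fat cells, averaged 14.30 (SD 0.26, n = 48) in fat and 6.09 (SD 0.07, n = 48) in liver, where 1 array detected it (adjusted p = 4.33e-125). Aoc3, the lipid droplet gene Cidec and leptin (Lep) were not detected in liver and were at least 148-fold, 47.6-fold and 45.7-fold higher in fat, and Plin4 was not detected in liver either. Cav1 (7.00), Lgals1 (6.56), Lpl (6.11), Tmem45b (5.92) and Sncg (5.88) followed. The apolipoprotein gene Apoa2 averaged 15.25 (SD 0.17) in liver and 6.34 (SD 0.88) in fat, where 10 arrays detected it (difference -8.91). Apoa1 (-8.42), Ambp (-8.10), Hpx (-7.96), Apoc3 (-7.89), Fga (-7.82), Kng1 (-7.55), Itih4 (-7.45), Ahsg (-7.42) and Ttr (-7.35) were next. In limma 10162 of 11718 probes differed (86.7%), 5612 higher in fat and 4550 in liver, and 2298 by more than 2-fold. The median of all probes was 0.04. With median centring in place of quantile normalization it was 0.26, and 8637 probes were then higher in fat and 2158 in liver, so small differences between the tissues depend on the scaling.

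Lists followed the tissues. All 14 hepatocyte, 13 bile acid and 17 cholesterol synthesis genes were higher in liver, as were 13 of 14 acute phase genes, 11 of 15 fatty acid oxidation genes, 8 of 12 unfolded protein response genes, 20 of 21 genes known as male-biased and 15 of 18 known as female-biased. Higher in fat were 14 of 17 adipocyte genes, 8 of 9 adipose expansion markers, 12 of 13 extracellular matrix genes, 8 of 9 preadipocyte and stroma genes, 9 of 9 endothelial genes and 8 of 12 macrophage genes. X inactivation and escape genes were higher in fat for 2 of 3, immediate early genes for 5 of 7, mesothelium for 5 of 7, T and B lymphocytes for 4 of 5, circadian clock for 6 of 11 and skeletal muscle for 2 of 2. Interferon response was higher in liver for 5 of 8 and ovary for 1 of 1, while gluconeogenesis and insulin response (4 in fat and 5 in liver of 10), thermogenic genes (3 and 2 of 5), the growth hormone and IGF axis (4 and 4 of 9), red blood cells (1 and 1 of 4), pancreas (0 and 1 of 2), proliferation (1 and 0 of 5) and the chromosome 2 candidates (19 and 15 of 38) had no clear majority. Lipogenesis was divided, with 10 of 18 higher in fat and 8 in liver, as was oxidative phosphorylation with 10 and 11 of 25. The medians of oxidative phosphorylation (0.03), X inactivation and escape (0.15), T and B lymphocytes (0.19), circadian clock (0.19), interferon response (-0.19) and ovary (-0.08), like those of the growth hormone, red blood cell, proliferation and chromosome 2 lists, were smaller than the move from 0.04 to 0.26 between scalings.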

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

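These results were singled out because a test of the difference itself, an interaction in limma, found that an effect was not the same in fat and liver. No test here was applied to single arrays as outliers, since every group holds more than 10 arrays. The tests of a strain variant under the probe, that of Gchfr included, were chosen after the interaction results had been seen.

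The effect of haplotype class differed between the tissues for 21 probes, and that of sex for 3243. With 1 probe per gene, the smallest adjusted p for class were those of Slpi (2.14e-07), Cep152 (2.94e-07), Gchfr (1.61e-05), Cst3 (3.53e-05) and Slc1a2 (0.000315). Among all probes the smallest was that of the second Gchfr probe (3.14e-13), and the second Slc1a2 probe had 2.14e-07. For sex the smallest were those of Sult2a2 (3.33e-88), Hsd3b5 (3.35e-69), Cyp2b9 (6.88e-61), A1bg (6.96e-59) and Slc22a26 (1.69e-56). Class labels were exchanged among mice of a sex, and sex labels among mice of a class. In each case only 1 of 100 splits, the real one, reached the real count (21 by class, highest other 3, and 3243 by sex, highest other 2). Labels given at random thus seldom gave so many probes. The counts do not exclude chance for single probes, and 10 of the 21 class probes lay on chromosome 2. Exchanging class labels also removed the chromosome 2 differences, which ease the adjusted threshold. The splits therefore do not exclude chance for the class probes outside chromosome 2. The 5 genes named for sex were near background in fat, and the difference by sex was not weighed further.

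The class effects called in 1 tissue only could reflect regulation that differs between fat and liver, or a strain variant under the probe that changes hybridisation. Such a variant would shift a probe alike in both tissues if both express the gene well. Of 31 class probes on chromosome 2 tested in both tissues, 11 were detected on every array of both, and 3 of these, Cst3, Trim44 and Cd59a, passed the interaction of tissue and class, with 6 at an unadjusted p under 0.05. The class means of Cst3 and Trim44 spanned 0.94 and 0.63 in liver, against 0.12 and 0.13 in fat. Those of Cd59a, called by class in liver only, spanned 0.34 in liver and 0.58 in fat. Cd59a was lower in class 4 than in class 1 in fat (10.33 and 10.72) and higher in liver (10.07 and 9.73). These values argue against a variant under the probe as the whole source for these 3 genes. For Slpi, Cep152 and Slc1a2 the tissue without a call is near background, and low expression there might hide a shift that the test with 3 genes does not address. Slpi, detected on 11 liver arrays, was not tested by class in liver. Its class means there kept the order of fat, from 6.49 in class 2 to 5.99 in class 3. For Gchfr both probes were higher in class 4 than in class 1 in fat (by 0.97 and 0.64), but in liver, where both were detected on 48 arrays, the second probe was lower (-0.62, adjusted p = 5.59e-06) and the main probe did not pass (-0.13, adjusted p = 0.999). Probes that part in liver are what a strain variant under the second probe would give. Such a variant alone would not give opposite directions, but together with a true rise in fat it could. In fat the second probe was detected on only 16 arrays, so that for Gchfr a variant stays open.

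For genes that differed by class in both tissues the same artifact was open. For class genes on chromosome 2 called by their brightest probe, no second probe was detected on every array of the tissue, a count of 0, so that a strain variant under the probe and a true difference in RNA cannot be told apart. Second probes, none of them detected on every array, did not pass for Tmem87a, Tmem127 and Ehd4 in fat (adjusted p of 0.815, 0.576 and 0.426) or for Tmem127 and Chp1 in liver (0.999 each). They did pass for Gchfr in fat (adjusted p = 4.41e-06, detected on 16 arrays) and for Slc1a2 in liver (adjusted p = 1.15e-05, detected on 34 arrays), which are not among the genes called in both tissues.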

How the results depend on the processing

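All alternatives were fixed before the data were examined, except those without the 3 least correlated arrays, without the male fat arrays with testis and epididymis genes, with the share of detected probes as a covariate, and with class labels of list tests exchanged within sex and scanning day, which were chosen after seeing the data. No named gene reversed in its class, sex, tissue or tissue by sex difference. Direction was not compared for the lists by sex, nor for the tissue by class genes, whose F statistic has no sign. The majority among sex calls in liver was higher in males (1417 higher in females, 1476 in males). It turned to females with the deposited values (1550 and 1339), with no detection filter (1290 and 1140), with the first digit of the mouse number (1016 and 1002) and without day 5 (891 and 821). Without day 6 the counts were equal (986 and 986). The majority for fat minus liver turned from fat (5612 and 4550) to liver (8997 and 9938) with no detection filter. The causes were not tested. Of the named genes, class calls stayed on the same side of the threshold in 496 comparisons with an alternative and were lost in the other 20.4%. Losses were most frequent with fewer arrays, as with females only (32), males only (22) and day 8 left out (11). Within 1 sex, class and scanning day were also partly tied, since each day held only some of the classes. Sex calls stayed in 711 and were lost in 4, and all 100 for tissue and 40 for interactions stayed. For lists by sex, 82 stayed, 11 were gained and 9 lost.

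The count for haplotype class in fat, 41 probes, moved to 65 with the deposited values, 21 without scanning day, and 83 with the first digit of the mouse number as a term, and the cause was not tested. In liver the 27 class probes became 14 when detection on all 48 arrays was required, which also left 1334 probes by sex in fat and 1794 in liver, whereas class in fat gave 51 probes, 26 of them among the 41, and the cause was not tested. Within 1 sex, 24 arrays remained, and class gave 2 probes in females and 11 in males in fat, and 2 and 13 in liver. That fall need not come from fewer arrays alone, as class and scanning day were partly tied within a sex. Leaving out a scanning day left 36 arrays and gave 14 to 55 probes for class in fat (21 without day 4, 22 without day 7, 14 without day 8), 16 to 23 for class in liver (16 without day 5), 970 to 1967 for sex in fat (970 without day 3, 1490 without day 4, 1318 without day 8) and 1712 to 2425 for sex in liver (1712 without day 5). For sex by class it gave 0 to 54 in fat (54 without day 7) and 0 to 24 in liver (24 without day 5, 1 without day 2), and the cause was not tested. Without scanning day as a term, sex by class gave 3 probes in fat and 316 in liver, and the cause was not tested. Shared class genes fell from 11 to 7 at a threshold of 0.01. With no detection filter fat minus liver gave 18935 probes, as more were tested, and tissue by class 13. Of 7 lists by sex in each tissue, an estimated correlation kept 3 in fat and 3 in liver, and fry gave 11 and 13. No list passed by class when class labels were exchanged within sex and scanning day (0 in fat and 0 in liver).

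With the mouse as a replicate block, fat minus liver gave 10132 probes, tissue by class 25 and tissue by sex 3330, at consensus correlations of -0.0258 and 0.0295, and the block kept all calls of both interactions and 10132 of the 10162 for fat minus liver. With scanning day as a random block fat minus liver gave 8620. Without the 3 least correlated arrays the counts were 32 and 27 for class and 2431 and 2463 for sex, in fat and liver. Without the male fat arrays with testis and epididymis genes they were 49 for class and 1861 for sex in fat, and with the share of detected probes as a covariate 59 and 30 for class. The share of class genes on chromosome 2 in fat ranged from 33.3% (deposited values) to 77.8% (threshold of 0.01), and was 100% in liver throughout. Fat minus liver with the deposited values was not run, because these had apparently been scaled within each tissue. Arrays with fewer detected probes, such as those of scanning day 2 (a mean of 6644), limit what can be seen for genes of low expression.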

Other observations

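The test of segments along chromosome 2 was chosen after the class results had been seen, as were the test of gene lists among genes that vary together in both tissues and the alternatives without the 3 least correlated arrays and without the male fat arrays with testis and epididymis genes.

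Fat and liver of the same mouse varied together for a small set of genes outside chromosome 2. Abhd1, Cops8, Tef, Ttc27, Hddc3, Ufc1 and Irgm2 had the highest correlations. With 1 probe per gene and chromosome 2 included, 30 of 5144 genes correlated above 0.6, which is not the same set as the 30 probes below. Among these genes were 4 of the 11 tested genes of the circadian clock list (Tef, Dbp, Arntl and Per3, Fisher's exact p = 3.02e-07, one-sided, adjusted over 23 lists 6.94e-06). The interferon list had 3 of its 4 (Igtp, Rsad2 and Gbp3, p = 7.13e-07, adjusted 8.2e-06). No other list passed, and genes are not independent replicates. On chromosome 2, Pdrg1 was among the highest. After class, sex, their interaction and scanning day had been removed, 30 of 5595 probes outside chromosome 2 (0.536%), on 14 chromosomes, correlated above 0.6 between the tissues and 0 below -0.6, and on chromosome 2 3 of 466 did (0.644%).

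The hypothesis was that differences segregating elsewhere in the genome are shared by the tissues of a mouse. Only 1 of 100 pairings of fat with liver arrays, the real one, had as many probes above 0.6, and the highest other had 1. Over all probes the tissues of a mouse were hardly alike, with a median correlation of 0.0681 against -0.00119 for other pairs, and 4 of 48 mice matched best with their own second tissue. With probes above 0.6 in the remaining mice alone, 38 of 48 did. That is consistent with segregating differences, but clock and interferon genes may also follow the hour of sampling or an immune state that both tissues share, which the test does not separate.

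Splits of the arrays, in which labels were exchanged, were counted 100 times for each result with the real one included. For class in fat (41 probes, highest other 1), class in liver (27, highest other 16), sex in fat (2314, highest other 2), sex in liver (2893, highest other 3) and fat minus liver (10162, highest other 7367), 1 of 100 splits reached the real count. Labels given at random thus seldom reached these counts, which does not exclude chance for single probes. Class labels were exchanged within sex but not within scanning day. For the fat class probes outside chromosome 2 the splits do not exclude chance, for the reason given below. The split with 7367 had exchanged the tissues of 34 of the 48 mice, against 18 to 30 in splits without a call. For sex by class the real count was 0, which all 100 splits reach by construction (highest other 4 in fat and 6 in liver), so that splits decide nothing there.

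The class genes of fat outside chromosome 2, all lowest in class 2, could reflect regulation by chromosome 2 or a few arrays that stand apart. Testis or epididymis cells in some male fat pads, or fewer macrophages or less fat mass in class 2, are further possibilities. Splits gave at most 1 such probe against 17, and 1 of 100, the real one, reached that count. Exchanging the labels also removed the chromosome 2 differences, which ease the adjusted threshold for other probes in the real data. The splits therefore do not exclude chance for these genes. Without the 3 least correlated arrays 4 of the 15 genes passed, with a median difference of 0.38 against 0.43, but leaving out 3 male arrays of the same classes at random gave 2 to 15 (median 5), and 43 of 100 draws gave 4 or fewer, so that the arrays that stand apart cannot be told apart from a loss of power. Without the 4 male fat arrays that detected at least 5 testis and epididymis genes, 9 of the 15 passed. Fewer arrays alone could also lower that count, so a part played by such cells stays open. The macrophage list (permutation p = 0.026, adjusted p = 0.351) and the adipose expansion list (p = 0.0418, adjusted p = 0.368) were lowest in class 2 like the 15 genes, as was the extracellular matrix list (p = 0.0149), but none passed by class. A bound written beforehand held that a p above the threshold would argue against them, and both lists met it. That bound was wrong, since a p above the threshold does not show that a list is unchanged. A shift in macrophage content and a difference in fat mass stay open.

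Genes of epithelial kind that were higher in male fat (Calml3, Sox9, Lcn2, Krt8 and Krt18) might come from testis or epididymis cells taken along with the fat pad. These genes are not a list fixed beforehand and were not tested as a set. Krt8 and Krt18 belong to the mesothelium list, which did not pass by sex in fat (camera adjusted p = 0.801) and whose member Wt1 was higher in females. Of 17 genes of the testis and epididymis list with a probe, 0 were detected on 12 or more fat arrays and the most on 10, so the bound set beforehand was not met. Cells taken along in only some of the 24 male fat pads would not meet it either, so the bound does not decide the matter. Prm1 and Defb42 were each detected on 9 male fat arrays, and no female array detected more than 1 of the list. At least 5 of the list were detected on 4 male arrays (10 on 2 of them). Calml3 was detected on all 4, but also on 7 male arrays with at most 1 of the list. Without these 4 arrays all 24 named sex genes of fat still passed, among 1861 probes, but male arrays that detected fewer of the list remained.

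Along chromosome 2, a further hypothesis was that the classes differ by 2 segments, so that genes early in the order would part classes 1 and 3 from 2 and 4, and later genes classes 1 and 2 from 3 and 4. The share of the variation held by the second parting minus that held by the first rose with gene order in fat (Spearman's rho 0.732 across 18 genes, one-sided permutation p = 0.0004) but not clearly in liver (0.273 across 21 genes, p = 0.114). The hypothesis called for a rise in each tissue, and with the higher p of 0.114 it stays open. Neighbouring genes are not independent replicates.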
